A study of Gallus gallus and Columba livia with 18 samples.

How the data were processed

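Whole retinas of chicken and pigeon embryos incubated at 37 °C were collected at E3, E5 and E8 (days 3 to 3.5, 5 to 5.5 and 8 to 8.5), with 3 libraries for each species and stage and 18 in all. Per the labels' protocols, each library came from 1 to 6 pooled retinas, RNA was extracted with Trizol, and 1 µg of total RNA went into a TruSeq stranded mRNA kit. Groups were taken from the labels. Per the submitters' processing notes, TopHat2, Bowtie2, Cufflinks and Cuffdiff were used, and the genome builds and annotations are not given in the sources used here.

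The deposited values are FPKM that the authors computed per gene, with 1 column per stage in each of 2 tables, per the file headers. Each column holds the authors' 1 pooled value for a stage, with no column per library, so replicates could not be compared. The chicken table has 24708 rows, of which 7092 carry no name and 307 join several names, and the pigeon table has 16652 rows, of which 2358 carry no name. Pigeon gene models have a median length of 957 bases, 89.9% of the lengths are multiples of 3, and 1971 models are shorter than 300 bases. Short models make FPKM depend on few fragments, so the number of smallest steps behind a value is given for some of the genes where it is low. Starts were counted from 0 in the tables and were converted to count from 1.

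Read totals are not given in the sources used here. As a stand-in for depth, each pigeon value was divided by the smallest nonzero value at that stage among models of nearly the same length, here called a smallest step. An FPKM of 4 to 6 in a model of about 1000 bases held a median of 34.5 steps at E3, 49.4 at E5 and 29.7 at E8. A step need not be 1 read, and the chicken table gives no lengths for the same calculation. Chicken sums of FPKM were 735656, 702306 and 676583 over the stages, and mitochondrial transcripts took 12.7%, 11.6% and 10.7% of them.

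Symbols listed once in a table were used, 11479 in chicken and 7790 in pigeon, and 517 and 336 of the rows were matched through an older symbol in a reference table of chicken gene names (assembly GRCg7b), from which names and no coordinates were taken. Refused were 3 older-symbol matches that pointed to a different gene. Both tables listed 6707 symbols once, and 5269 of these reached an FPKM of 1 in both species.

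The planned tests, limma on log2(FPKM + 1) and camera on gene lists, need a value per library and could not be used. In their place, changes of log2(FPKM + 1) between stages were computed for genes with an FPKM of at least 1 at 1 stage or more and above 0 at both compared stages, and genes with a change of at least 1 in size were counted. Differences between species were pigeon changes minus chicken changes. The numbers of genes left out because 1 of the compared stages was at 0 were 173 and 134 in chicken and 269 and 430 in pigeon, from E3 to E5 and from E5 to E8. The median change of a list was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, for lists with at least 5 compared genes, and a list was described as inside the random range between percentiles 2.5 and 97.5. For lists whose median from E3 to E8 lay outside the random range on the same side in both species, and that had at least 5 genes shared by both tables, the part of the change reached at E5 was the list score at E5 minus that at E3, over the score at E8 minus that at E3.

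Before the data were examined, 23 gene lists, the comparisons, the rule for naming genes and the first set of alternatives below were fixed. The lists cover retinal progenitors and eye field, proneural and neurogenic genes, the Notch pathway, ganglion cells, photoreceptors, amacrine and horizontal cells, bipolar cells and Müller glia. Others cover S phase, G2 and mitosis, synapse, glycolysis, the respiratory chain, patterning and retinoic acid, growth factors of the insulin-like family, and immediate early and heat shock genes. Markers of other cells cover pigment epithelium, lens, erythroid cells, endothelium, mesenchyme, leukocytes and optic nerve glia. Some genes stand in several lists, so the lists are not independent of each other. Genes were named when they were among the 5 highest or 5 lowest changes, among the 4 largest of a list, or among 16 fixed genes, with an FPKM of at least 5 in the higher stage for the first kinds. That rule was written for genes past a test, and its form for tables with 1 value per stage, which ranks genes by size of change, was used. Genes that fall outside it are named only in counts or as members of the artefact checks, and results for some genes that it takes in are not reported here.

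Alternatives planned and run were pseudocounts of 0.1 and 5, no filter and an FPKM of at least 5, median-ratio scaling and quantile normalisation. Alternatives chosen after seeing the data were a change of at least 2, values of 0 included, pigeon models of at least 300 bases, all genes but those of 6 other-tissue lists (pigment epithelium, lens, erythroid, endothelium, mesenchyme and leukocytes), a mean FPKM of at least 20 without a pseudocount, pigeon values divided by the shared-gene median ratio of 2.11, and the highest row of each symbol. On simulated data for E5 against E3, the counting found 98.6% of genes changed 3-fold in chicken (13022 genes) and 98.6% in pigeon (11620 genes) and 100% of those changed 4-fold and 8-fold, and counted 0 unchanged genes. Of unchanged simulated lists, 6% in chicken (8519 genes) and 4% in pigeon (6522 genes) fell outside the middle 95%. The simulated noise was independent between genes with an SD of 0.2 log2. Changed genes were drawn from those with an FPKM of at least 5. Against a cutoff of 1, noise of that size largely fixes the counts in advance. These figures check the calculation and give no error rate for the data, which hold no replicate values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.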

Results

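The series followed gene expression in the developing retina of 2 birds, the chicken (Gallus gallus) and the pigeon (Columba livia). Messenger RNA was sequenced from retinas taken at 3 stages of incubation. The first stage, here called E3, covers embryonic days 3 to 3.5, the second, E5, days 5 to 5.5, and the last, E8, days 8 to 8.5. The 18 libraries fall into 6 groups of 3, one group per species and stage, and each library came from 1 to 6 whole retinas. The deposited tables give 1 pooled FPKM value (fragments per kilobase of transcript, scaled to the number of mapped fragments) per gene and stage, with 24708 rows in the chicken table and 16652 in the pigeon table. No difference reported here therefore has a replicate check, and no SD between replicates, n or p-value stands beside any value. Read totals are not given in the sources used here, and the low-value steps of the pigeon table put an FPKM of 4 to 6, in a gene of about 1000 bases, at a median of 34.5 smallest steps at E3, 49.4 at E5 and 29.7 at E8.

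Changes between stages are differences of log2(FPKM + 1), which understate the change of genes with low values. A gene was counted as higher or lower when this change was at least 1 in size, and a gene listed at 0 at a compared stage was left out, since 0 can be a failed estimate. For each of 23 gene lists fixed before the data were examined, the median change was set among 10000 random lists of the same size matched on mean expression, as a description of these values. The 4 median changes over all genes, from E3 to E5 and from E5 to E8 in each species, lay between −0.00341 and 0.000457. Counts of genes past 1 depend on the pseudocount, and in chicken from E3 to E5 their total of 431 became 1134 with a pseudocount of 0.1 and 123 with 5. The tables of the 2 species were normalised separately, so levels in one were never tested against levels in the other.

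Of 16 genes fixed in advance as landmarks of retinal development, ATOH7, SOX2, CCND1, ISL1, GAP43, SNAP25 and RXRG were listed once in both tables, and HES5 and NEUROD1 in the chicken table alone. HES1 and CRX were not matched to either table and were not analysed here. NEUROG2 stood in 2 pigeon rows, with FPKM of 0 at all stages in one and 0, 6.70 and 129.6 at E3, E5 and E8 in the other, and OTX2 stood in 2 pigeon rows that went opposite ways from E5 to E8, 86.5 to 7.55 and 48.2 to 202. NEUROD4 was listed at 0 at all 3 stages in chicken. ATOH7, which encodes the transcription factor needed for retinal ganglion cells, stands in a chicken locus on chromosome 6 from position 11588940 to 11643284 (XLOC_019146). In pigeon it lies on scaffold645 from 414244 to 414696 (Cli_R013085). The chicken locus is far longer than the pigeon model, and whether it takes in other transcripts was not tested. The genome builds are not given in the sources used here.

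**Figure D1:**
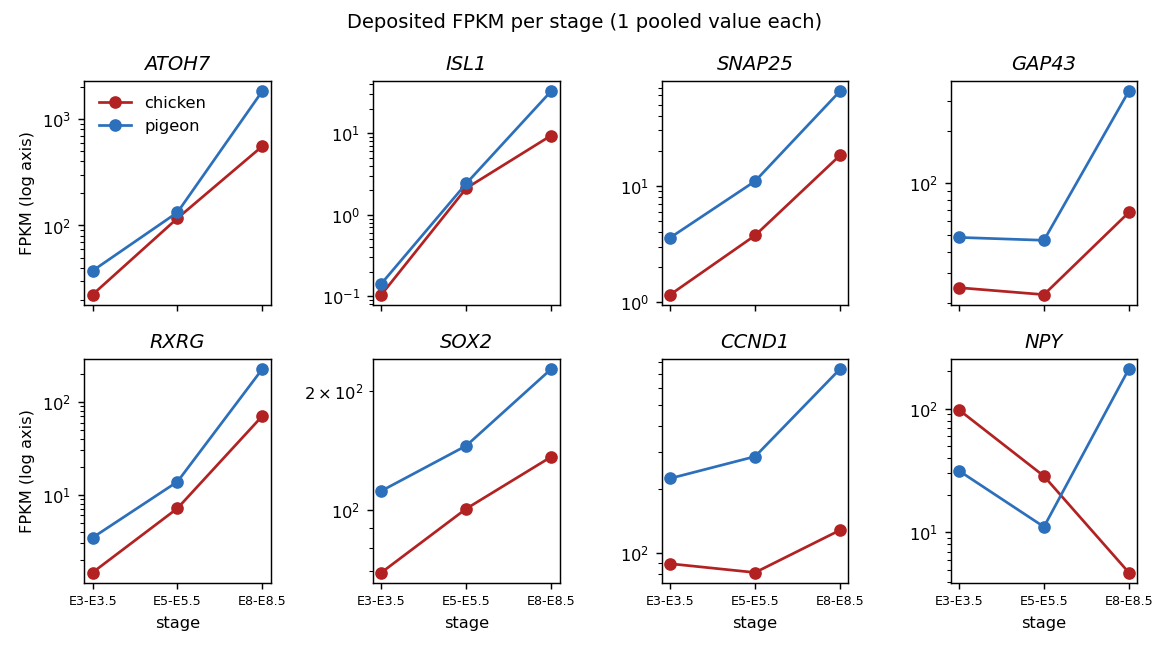
Deposited FPKM (log axis, own range in each panel) of 8 genes at E3, E5 and E8, with chicken in red and pigeon in blue. Each point is the authors' 1 pooled value for that species and stage, so no error is drawn, and the species come from separately normalised tables. From E5 to E8, NPY went from 28.5 to 4.74 in chicken and from 11.1 to 209 in pigeon.

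From E3 to E5 in chicken, genes of neurogenesis were higher, and 4 of 20 progenitor and eye field genes were lower. ATOH7 was at 22.4 FPKM at E3 and 117 at E5, a log2 change of 2.33, and NEUROD1, a neurogenic transcription factor, had a change of 2.08. HES5, an effector of Notch signalling in progenitors, went from 6.39 to 53.4, and LFNG, which modifies the Notch receptor, from 21.3 to 115. LIN28 (LIN28A), an RNA-binding protein of early embryonic cells, went from 13.7 to 1.23, and PRTG, a cell-surface receptor of early neural tissue, from 42.9 to 7.10. GBE (3.59), CKMT1A (3.03) and GPR143 (2.91) were among the 5 highest changes, and CLDN1, a tight junction protein (−3.76), IGFBP2 (−2.95) and RASD2 (−2.44) among the 5 lowest. Among 14490 genes compared, 286 were higher at E5 by at least 1 log2 unit and 145 were lower.

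By list, 8 of 13 proneural and neurogenic genes were higher by at least 1 and none was lower, with a median change of 1.29, above all 10000 random lists. Of 20 Notch pathway genes 5 were higher, among them DLL4 (1.65) and NOTCH1 (1.36), and of 21 retinal ganglion cell genes 8 were higher, among them NRN1 (2.08), STMN2 (1.99) and the neurofilament genes NEFM (1.35) and NEFL (1.29). The medians of these lists, 0.24 and 0.66, also lay above all random lists. RXRG, a nuclear receptor of early cones, went from 1.45 to 7.14 FPKM, and 4 of 10 photoreceptor genes were higher and 1 was lower (median 0.44, above 9997 random lists). NEUROD1 and OTX2, among the photoreceptor genes that were higher, are also members of the proneural list, as is DLL4 of the Notch list. Results of these lists are therefore not separate from each other. The bipolar cell list (8 members, median 0.44) and the Müller glia list (13 members, median 0.44) lay above 9991 and 10000 random lists, while the amacrine and horizontal cell list (14 members, median 0.11) and the synapse list (20 members, median 0.18) lay inside the middle 95% of them, the latter at percentile 97.52 and outside with a pseudocount of 0.1. Of 20 progenitor and eye field genes 4 were lower and 1, HES5, was higher, and the list's median of −0.19 lay below all random lists.

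Cell cycle genes differed little, and none of 29 S phase genes and none of 25 G2 and mitosis genes differed by 1, with medians of −0.02 and −0.04. CCND1 was at 89.2 and 81.1 FPKM, and SOX2 at 69.5 and 101. Of 30 genes of retinal patterning and retinoic acid 2 were higher by at least 1, among them BMP2 (1.76 to 5.03 FPKM), and 1 was lower, although 22 had a negative change. ALDH1A3, a retinoic acid synthesising enzyme listed as ALDH6, went from 347 to 109.5 FPKM. The glycolysis list had a median of −0.24, below all random lists, with LDHA at −0.42 and LDHB at −0.43. The respiratory chain list (47 members) had a median of 0.09, above 9999 random lists, with no member past 1. In the growth factor list, IGFBP2 (−2.95) and IGF2 (−1.45) were lower, and the list median of −0.06 lay inside the random range. The immediate early and heat shock list had a median of −0.15, below 9805 random lists, with IER5 at 1.07 and HSP90AA1 at −0.26. Whether handling of the samples plays a part in this list was not tested.

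Lists of tissues next to the retina had positive medians at E5 in chicken, along with the neurogenic genes. The pigment epithelium genes TYR, which encodes the melanin enzyme tyrosinase, and MLANA went from 5.43 to 45.7 and from 7.01 to 57.1 FPKM, and 7 of 12 members of that list were higher by at least 1 (median 1.57, above all random lists). All 6 erythroid genes compared had a positive change and 5 were past 1, with HBG2 (beta globin) at 294 and 753 FPKM. Lens (11 members, median 0.65), endothelium (9 members, median 0.58) and periocular mesenchyme (23 members, median 0.49) lay above 10000, 9987 and 10000 random lists, with 4, 2 and 5 members higher by at least 1 and 1 mesenchyme gene lower. Leukocyte genes (5 members, median 0.25) lay inside the random range, and the 3 optic nerve glia genes, too few for a percentile, had a median of −0.42. Haemoglobin genes are close copies of each other, and how the counting split reads among them is not given in the sources used here, so their single values are uncertain.

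From E5 to E8 in chicken, genes of differentiating neurons were higher and genes of pigment epithelium, lens, blood, vessels and mesenchyme were lower. ATOH7 reached 555 FPKM (2.24), TFAP2D, a transcription factor, went from 1.90 to 32.2, and BLIMP-1 (PRDM1), a factor of early photoreceptors, from 1.82 to 20.5. SLC1A3 (3.00) and BAIAP2L1 (2.88) were also among the 5 highest. ASL1, which encodes the lens protein delta-crystallin, went from 625 to 2.33 FPKM, LUM, a matrix protein of the cornea and connective tissue, from 44.3 to 0.106, and TYR from 45.7 to 1.74. Of 14540 genes compared, 658 were higher and 648 lower by at least 1, and 79 and 141 by at least 2.

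Of 21 retinal ganglion cell genes 13 were higher by at least 1 and none was lower (median 1.35), with STMN2 at 2.37, SNCG at 2.20 and GAP43, a growth cone protein, at 1.55. Proneural genes (8 of 13 higher, median 1.21), photoreceptor genes (6 of 10 higher and 1 lower, median 1.70), bipolar cell genes (4 of 8 higher, median 1.11) and synapse genes (8 of 19 higher, median 0.87) also lay above all 10000 random lists. RXRG had a change of 3.13 and THRB, the thyroid hormone receptor of cones, 2.70, and in the synapse list SYT4 (2.25) and SNAP25 (2.02) were higher. The amacrine and horizontal cell list (median 0.47) lay above 9982 random lists, the Notch list (0.25) above 9985 and the progenitor list (0.07) above 9850, with FGF19 at 2.04 and HES5 at 1.61. Müller glia genes had a median of 0.12, inside the random range, and went both ways, with SLC1A3, a glial glutamate transporter, at 3.00 and RLBP1, which pigment epithelium also expresses, at −1.11. OTX2 had a change of 0.87.

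S phase genes (median 0.03) lay inside the random range, although at percentile 98.1 with the highest row taken for each symbol listed more than once, a choice made after the data were seen, while 20 of 25 G2 and mitosis genes had a positive change (median 0.24, above all random lists) with none past 1. The patterning list had 5 of 30 genes lower and 1 higher (median −0.33, below all random lists), among them BMP4 (−3.17) and the retinoic acid genes ALDH1A2 (−2.38), CYP26B1 (−2.16) and STRA6 (−1.83). The growth factor list had a median of −0.39, below 9992 random lists, with MYC at −1.45. Glycolysis (−0.07) and respiratory chain (−0.04) genes lay inside the random range, and the heat shock list (−0.49) lay below 9998 random lists.

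The other-tissue lists of chicken were lower at E8 where the neuronal lists were higher. Of 12 pigment epithelium genes 10 were lower (median −2.62), and of the erythroid list all 6 were lower (median −3.92). Lens had 5 of 9 lower and 1 higher (median −1.45), endothelium 7 of 9 lower (median −1.61) and mesenchyme 15 of 22 lower and 1 higher (median −1.62), and each of these 5 medians lay below all random lists. FOXC2 went from 35.6 FPKM to 0.119, and CDH5, an adhesion protein of endothelium, from 8.01 to 0.127. COL5A1 went against its list, at 37.8 and 58.5. Leukocyte genes had a median of −0.83, below 9768 random lists, and the optic nerve glia genes a median of −0.99.

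In pigeon, ATOH7 (37.5 to 133 FPKM, 1.80), POU4F1, a ganglion cell transcription factor (3.89 to 18.8), and RXRG (3.45 to 13.8) were higher at E5 than at E3. MME, a membrane peptidase, went from 7.21 to 55.7, and PENK, which encodes proenkephalin, from 2.65 to 18.9. FST, a secreted inhibitor of activin, had a change of −2.31, ISM1 −1.95, BZRPL1 −2.23 and TMEM90A −1.94, and SPON2 went from 7.49 to 0.633. Among 11948 genes compared, 181 were higher by at least 1 and 163 lower.

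Of 8 proneural genes 3 were higher by at least 1 (median 0.78, above all random lists), with MYT1 at 1.46 and HES6 at 1.04. Ganglion cell genes (3 of 11 higher, median 0.31), photoreceptor genes (2 of 5 higher, median 0.55), Müller glia genes (1 of 7 lower, median 0.22), progenitor genes (7 members, median 0.34) and G2 and mitosis genes (20 members, median 0.09) lay above 9940, 9959, 9907, 9999 and 9928 random lists. With the highest row of each symbol, the photoreceptor list lay at percentile 93.1, inside the random range, and the patterning (0.73), growth factor (1.19) and respiratory chain (97.9) lists lay outside it. The lists for Notch (0.06), amacrine and horizontal cells (0.18), synapse (0.15), S phase (0.01), respiratory chain (0.06), patterning (0.09) and growth factors (−0.02) had medians inside the random range with symbols listed once. IGFBP2 (−1.57), PAX2, a factor of the optic stalk (−1.02), FOS (−1.42) and ATF3 (−1.07) were lower, and the heat shock list had a median of −0.13, at percentile 2.72. Bipolar cell, glycolysis, leukocyte and optic nerve glia lists had under 5 compared members, with medians of 1.58, −0.15, 0.57 and −0.70.

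The 5 lists of neighbouring tissues with enough members had negative medians in pigeon at E5. Pigment epithelium genes had a median of −0.03, with MLANA at 2.59, GPR143 at 1.19 and TYR at −0.09. MLANA and FAM165A (2.07), 2 of the 5 highest genes, rest on short gene models of 306 and 150 bases and on 1.1 and 1.08 smallest steps at E3, and BZRPL1 rests on 1.76 steps at E5. Mesenchyme (11 members, median −0.46), endothelium (7 members, −0.54) and erythroid genes (5 members, −0.50) lay below 9996, 9896 and 9878 random lists, while lens (6 members, −0.25) lay inside the random range. The endothelium list lay at percentile 5.24 with a pseudocount of 0.1, inside the random range. The embryonic globin gene HBZ went from 2119.6 to 657 FPKM, with the same caution on close copies, and DCN, a matrix protein, from 43.2 to 19.2.

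From E5 to E8 in pigeon, neuronal and photoreceptor genes were higher by larger steps than from E3 to E5. ATOH7 went from 133 to 1827 FPKM (3.77), PRDM1 from 2.12 to 84.4, NR2E3, a photoreceptor nuclear receptor, from 0.294 to 31.3, and TFAP2D from 2.28 to 146. ACBD7, which encodes an acyl-CoA binding protein, went from 28.8 to 1985, and SAMD7 had a change of 4.58. At the other end, HBZ went from 657 to 0.615, LUM from 79.7 to 1.18, TYR from 68.5 to 1.02 and MME from 55.7 to 2.04, and SLC38A8 had a change of −4.73. Of 11820 genes compared, 950 were higher and 857 lower by at least 1, and 262 and 181 by at least 2.

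Of 12 ganglion cell genes 11 were higher by at least 1 (median 2.10), with ISL1 at 3.30 and GAP43 at 2.86. Proneural genes (6 of 8 higher, median 2.34) and photoreceptor genes (4 of 7 higher, median 3.54) lay, with the ganglion cell list, above all random lists. Synapse genes (8 of 11 higher, median 1.09) lay above 9999 and amacrine and horizontal cell genes (6 of 10 higher and 1 lower, median 1.08) above 9992, with SNAP25 at 2.47, SV2B at 2.45 and CALB1, a calcium-binding protein, at 3.51, while PENK went the other way at −3.05. The progenitor list (median 0.44, above 9940) included CCND1, at 286 and 739.7 FPKM, and HMGA2, a chromatin protein, at −1.81. G2 and mitosis genes had a median of 0.28, above 9980, with NUSAP1 at 1.19, and S phase genes a median of −0.09, inside the random range.

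Of 6 patterning genes all had a negative change (median −0.81, below 9994 random lists), with STRA6 at −3.63, and of 8 growth factor genes 4 were lower and 1 higher (median −0.78, below 9984), with MYC at −2.09. When the highest row of each symbol was taken, the growth factor list lay at percentile 6.00, inside the random range, and the Notch and Müller glia lists at 99.5 and 99.66, outside it. SLC2A1, a glucose transporter, went from 1231 to 372 FPKM. Medians of the Notch (0.20), Müller glia (0.44), respiratory chain (−0.11) and heat shock (−0.19) lists lay inside the random range with symbols listed once. The 4 compared members of the bipolar cell, glycolysis, erythroid and optic nerve glia lists had medians of 1.16, −0.42, −0.91 and 0.68, and the 3 of the leukocyte list 0.72.

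As in chicken, the neuronal lists of pigeon moved against markers of other tissues at E8. Pigment epithelium genes (6 of 7 lower, median −3.33) and mesenchyme genes (7 of 10 lower and 1 higher, median −1.86) lay below all random lists and endothelium genes (3 of 5 lower, median −1.19) below 9969, whereas lens (5 members, median −0.33) lay inside the random range. The lens genes higher by at least 1 were CRYAB (3.05) and PROX1 (2.13), and PROX1 is also a member of the amacrine and horizontal cell list. MLANA was listed at 0 at E8. COL1A2, a collagen of connective tissue, went from 47.7 to 4.54 FPKM and FBLN1 from 40.7 to 1.66, while PDGFRA went from 5.26 to 25.2.

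**Figure D2:**
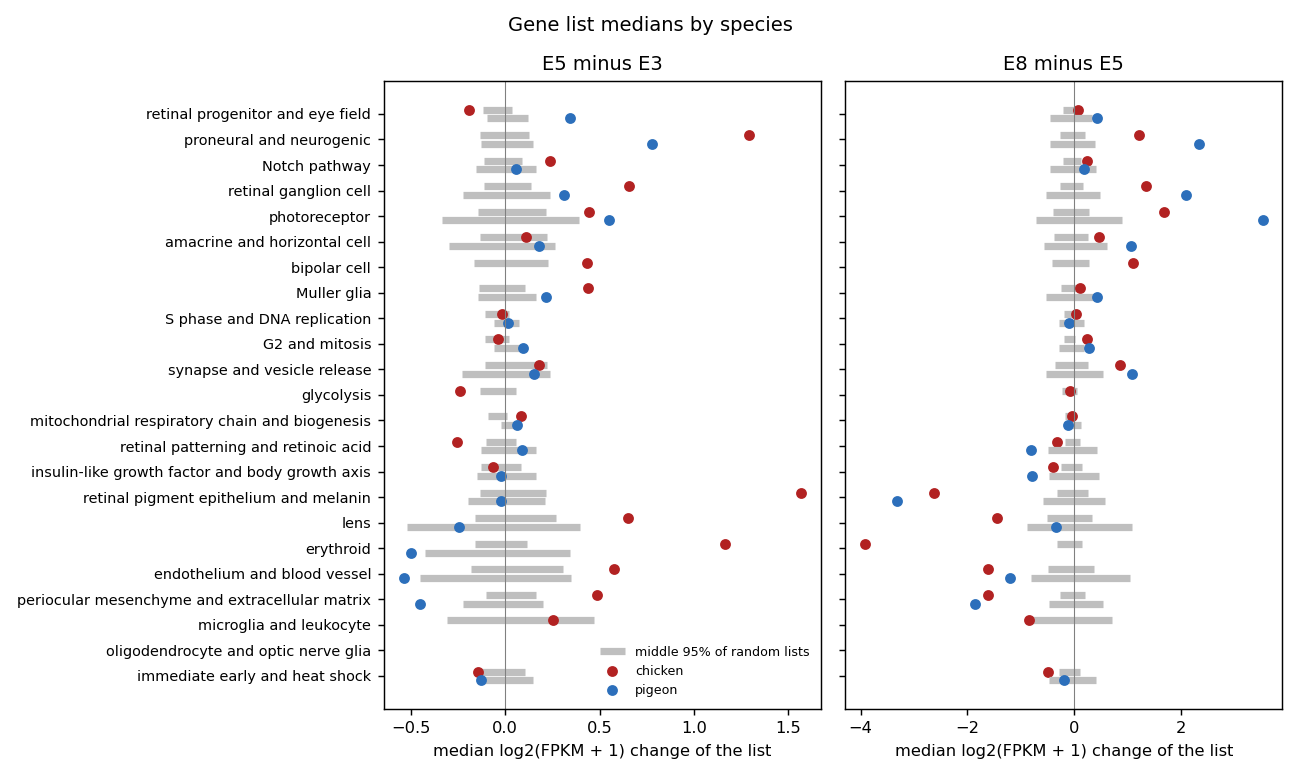
Median log2(FPKM + 1) change of each gene list with at least 5 compared genes, from E3 to E5 (left) and from E5 to E8 (right), with chicken in red and pigeon in blue. Grey bars span the middle 95% of 10000 random lists matched on size and mean expression. The pigment epithelium list sits at 1.57 in chicken (12 genes) and −0.03 in pigeon (8 genes) on the left, and at −2.62 (12 genes) and −3.33 (7 genes) on the right. Each species has its own set of compared genes, so red and blue points of a list do not rest on the same genes.

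The series set the 2 species side by side at the same embryonic days, which need not be the same point of development. From E3 to E5, 5231 genes listed once in both tables could be compared. Levels of the 2 species come from separately normalised tables, and only changes were compared. The change of pigment epithelium genes was lower in pigeon than in chicken, and TYR went from 5.43 to 45.7 FPKM in chicken and stood at 73.1 and 68.5 in pigeon, a pigeon minus chicken difference of −2.95. HBZ went from 115 to 234 in chicken and from 2119.6 to 657 in pigeon (−2.70), and CXCL12, a chemokine, had a difference of −2.44. MOXD1 (1.90), IGFBP2 (1.37) and IGF2 (1.23) lay on the other side, and the chicken change was the lower one in each, at −1.78, −2.95 and −1.45. Altogether 39 genes had a change at least 1 higher in pigeon and 98 a change at least 1 lower, while at a mean FPKM of at least 20 without a pseudocount, chosen after the data were seen, 6 were higher and 6 lower.

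Of the lists with at least 5 genes, 5 lay outside the middle 95% of random lists, all with a lower median than the random lists. All 8 pigment epithelium genes had a negative difference (median −1.13, below all random lists), as did 8 of 11 mesenchyme genes (median −0.75, below 9999), with PITX1 at −2.04. Müller glia genes (5 of 6 negative, median −0.45, below all random lists) included CA2, at 1792 and 2428 FPKM in chicken and 1891 and 929.9 in pigeon. Proneural genes had a median of −0.54, below 9997 random lists, with HES6 at −0.91, SRRM4 at −0.59 and ATOH7 at −0.54, and none of the 7 differed by 1. Respiratory chain genes had a median of −0.02 against a random median of 0.06, below 9958 lists. Ganglion cell (−0.09), progenitor (0.12), Notch (−0.05), amacrine and horizontal cell (−0.07), synapse (0.14), S phase (0.07), G2 and mitosis (0.10) and growth factor (0.12) lists, and the heat shock list, lay inside the random range, although the progenitor list lay at percentile 99.99 with the highest row of each symbol. Among the 5 highest differences, FAM103A1 (2.54), FAM165A (2.23), CHSY1 (1.72) and HSBP1 (1.49) rest on pigeon models of 171, 150, 393 and 216 bases and on 6.41, 1.08, 3.16 and 3.29 smallest steps at E3. HIGD2A (−2.10) and CXCL12, among the 5 lowest, rest on models of 180 and 207 bases and on 1.89 and 5.501 steps at E3.

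From E5 to E8, 5212 shared genes could be compared, and the neuropeptide gene NPY had the largest difference, 28.5 to 4.74 FPKM in chicken and 11.1 to 209 in pigeon (6.48). ACBD7 went from 34.4 to 72.0 in chicken and from 28.8 to 1985 in pigeon (5.02). ATOH7 (1.54), ISL1 (1.57) and GAP43 (1.31) were higher at E8 in both species, by more in pigeon. SYT10 (3.11), CALML4 (3.04) and CRYAB (2.87) completed the 5 highest. BAIAP2L1 (−4.98) was higher at E8 in chicken and lower in pigeon, and HBZ (−4.41) was lower in both by more in pigeon. PENK (−3.93), PID1 (−3.13) and SFRP2, a secreted Wnt modulator (−2.96), were lower in pigeon by at least 1, with chicken changes of 0.88, −0.15 and −0.49. The pigeon change was at least 1 higher than the chicken change in 264 genes and at least 1 lower in 165. The pigeon models of NPY and ACBD7 are 273 and 252 bases long, the pigeon values of CRYAB and CALML4 at E5 held 2.57 and 6.68 smallest steps, and that of HBZ at E8 held 1.031.

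Proneural genes (all 7 positive, median difference 0.86, above 9998 random lists) and ganglion cell genes (8 of 9 positive and 5 past 1, median 1.00, above 9978) had the higher change in pigeon, with ISL1 at 1.57 and HES6 at 0.91. Pigment epithelium genes had a median of −1.01, below 9991 random lists, and 5 of 7 were negative. The list lay inside the random range under some alternatives, at percentile 8.55 with a pseudocount of 0.1, at 10.5 with the highest row of each symbol, and at 10.4 with pigeon values divided by the median species ratio of 2.11, and with that division the differences of TYR (−1.01), OCA2 (−1.21) and GPR143 (−1.05) came to −0.40, −0.39 and −0.22. Those of EBF3 (1.00) and SV2B (1.40) came to 0.45 and 0.98. Amacrine and horizontal cell (0.76), Müller glia (−0.24), S phase (−0.15), G2 and mitosis (0.26), synapse (0.44), Notch (0.29), progenitor (0.13), respiratory chain (0.04), growth factor (−0.14), mesenchyme (0.10) and heat shock (−0.12) lists lay inside the random range. Of these, mesenchyme lay outside it with a pseudocount of 0.1 (percentile 98.18) and with the division (99.54), and the amacrine and horizontal cell (99.08) and G2 and mitosis (97.85) lists with the highest row of each symbol.

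**Figure D3:**
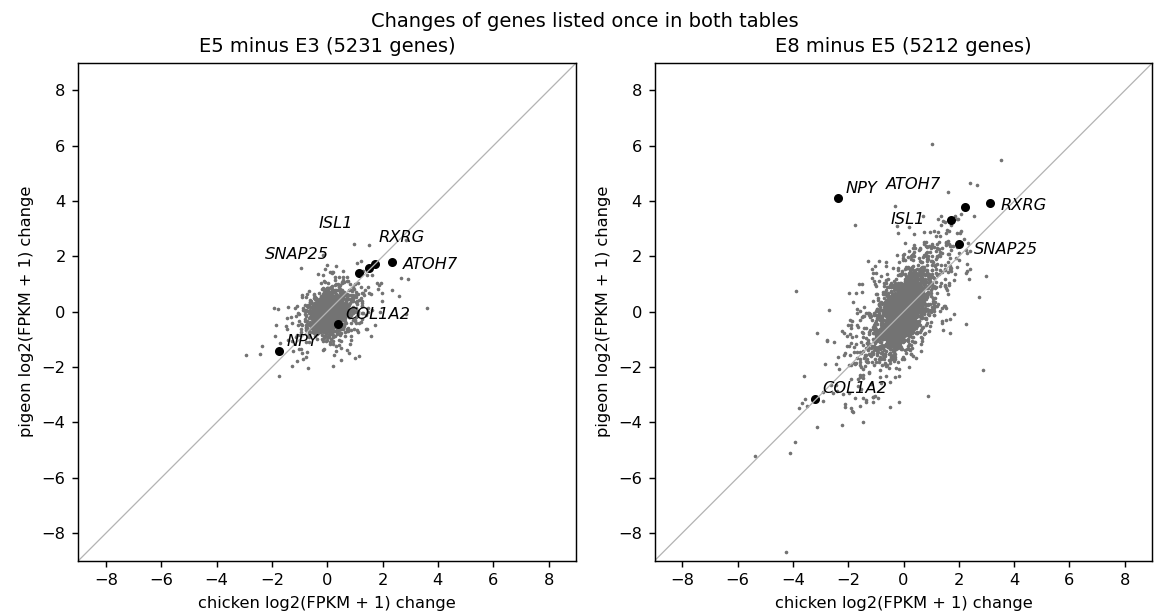
Change of each gene listed once in both tables, chicken on the x axis and pigeon on the y axis, as differences of log2(FPKM + 1) from E3 to E5 (left, 5231 genes) and from E5 to E8 (right, 5212 genes), with equal changes on the grey diagonal. Each small point is 1 gene, 6 genes are marked in black, and the Pearson correlation across genes was 0.312 on the left and 0.644 on the right.

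Genes that differed between E5 and E8 overlapped between the species. Of shared genes, 157 were higher by at least 1 in chicken and 353 in pigeon, with 112 in both against 10.6 for independent lists, and 194 and 302 were lower, with 118 in both against 11.2. From E3 to E5, 74 were higher in chicken and 46 in pigeon with 16 in both (0.651 for independent lists), and 31 and 44 were lower with 12 in both (0.261). Genes lower in chicken and higher in pigeon from E5 to E8 numbered 12, and 1 gene, BAIAP2L1, went the opposite way. Across shared genes, 4 correlations of changes were computed, and genes are not independent replicates. Pearson's r was 0.312 (Spearman's rho 0.220) for the E3 to E5 changes of both species and 0.644 (0.560) for the E5 to E8 changes. Across steps it was 0.193 (0.144) for pigeon E3 to E5 with chicken E5 to E8, and 0.115 (0.0856) for pigeon E5 to E8 with chicken E3 to E5.

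From E3 to E8, 961 of 14451 chicken genes were higher and 764 lower by at least 1, and in pigeon 1107 and 1011 of 11785. Ganglion cell genes were higher in 16 of 21 cases in chicken (median 2.00) and 10 of 11 in pigeon (2.49), and proneural genes in 11 of 13 (1.94) and 6 of 8 (2.85). Pigment epithelium genes had medians of −1.28 in chicken (12 genes) and −2.98 in pigeon (7 genes). Mesenchyme genes had medians of −1.01 (22 genes) and −2.70 (10 genes), so the medians of the species rest on unlike sets of genes. Over 10 shared mesenchyme genes, the median pigeon minus chicken difference was 0.10, at percentile 58.5 and inside the random range. In the differences between species, 297 genes were at least 1 higher in pigeon and 238 lower among 5207. Proneural genes (0.94), ganglion cell genes (0.81) and amacrine and horizontal cell genes (0.94) lay above 9998, 9901 and 9852 random lists, and Müller glia (−0.75) and pigment epithelium (−2.50) below 9996 and 10000. With a pseudocount of 0.1 the first 3 lay inside the random range, at percentiles 60.4, 92.3 and 84.3, as did proneural genes with the highest row of each symbol (38.5) and ganglion cell genes with the division of pigeon values (96.2).

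The part of the E3 to E8 change already reached at E5 was computed for 7 lists from the mean log2(FPKM + 1) of the genes shared by both tables. For proneural genes it was 40.9% in chicken and 23.0% in pigeon (7 genes), for ganglion cell genes 36.3% and 25.9% (9 genes), and for synapse genes 22.9% and 6.81% (10 genes). G2 and mitosis genes gave −23.4% and 11.4%, pigment epithelium genes −153% and −14.9%, and mesenchyme genes −12.9% and 14.0%, where a negative value means that E5 lay outside the range from E3 to E8. The G2 and mitosis values rest on small E3 to E8 changes of the list score, 0.198 in chicken and 0.513 in pigeon. The immediate early and heat shock genes gave 29.1% and 56.8%, and with an FPKM of at least 5 the order turned, at 29.97% and 22.9%. With a pseudocount of 0.1 the pigeon synapse value came to −0.598%, and with an FPKM of at least 5 to 21.6% (27.5% in chicken). With 1 value per stage these percentages have no error, and the difference between the species was not tested.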

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

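The contrast that singled out these genes was planned, and they were picked after their values were seen, as named genes whose changes were at least 1 in size and went opposite ways in chicken and pigeon. With 1 pooled value per stage, none of these differences was tested.

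From E5 to E8, NPY was lower in chicken (28.5 to 4.74 FPKM) and higher in pigeon (11.1 to 209), a difference of 6.48 in log2 change. The gene lies on chicken chromosome 2 from 31391882 to 31401500 and on pigeon scaffold671 from 100388 to 105775, and its pigeon model of 273 bases held 10.9 smallest steps at E5 and 127 at E8. SYT10, a synaptotagmin, was lower in chicken (17.1 to 6.42) and higher in pigeon (4.04 to 16.8), a difference of 3.11. BAIAP2L1 went the other way, from 2.28 to 23.1 in chicken and from 35.3 to 7.45 in pigeon, a difference of −4.98.

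From E3 to E5, the globin gene HBZ was higher in chicken (115 to 234 FPKM) and lower in pigeon (2119.6 to 657), a difference of −2.70. It lies on chicken chromosome 14 from 12722374 to 12724596 and on pigeon scaffold306 from 2890360 to 2892385. No explanation was tested for these 4 genes.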

How the results depend on the processing

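Changes of at least 2, inclusion of values of 0, pigeon models of at least 300 bases, removal of other-tissue lists, the mean FPKM of 20, the division of pigeon values and the highest row of each symbol were chosen after the data were seen, as were tolerances of 0.05 for a correlation and 5 points for a share. No paired analysis was possible because the tables hold 1 value per stage and no replicate columns. For the same reason the fit without a variance trend, the replicate block, leaving out each library, the fits of 2 stages or of each species alone, the estimated correlation and fry were not run. A change of at least 1, without an adjusted p, became the main rule. The low values behind each gene set the limit of depth.

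Counts were within 1.5 times of the main ones under median-ratio scaling, quantile normalisation, no filter and removal of other-tissue lists. The same held for pigeon models of at least 300 bases and division of the pigeon values. Without the filter, counts within a species were fixed in advance, since with a pseudocount of 1 a counted gene must exceed an FPKM of 1. Only differences between species could move, to 172 from E3 to E5, 511 from E5 to E8 and 646 from E3 to E8. With a pseudocount of 0.1, the totals of 431 (chicken) and 344 (pigeon) from E3 to E5 and of 137 for their difference became 1134, 693 and 262, and the chicken totals of 1306 from E5 to E8 and 1725 from E3 to E8 became 2421 and 2938. With a pseudocount of 5, chicken, pigeon and difference gave 123, 113 and 36 from E3 to E5, 421, 1049 and 201 from E5 to E8 (main 1306, 1807 and 429) and 626, 1227 and 288 from E3 to E8 (main 1725, 2118 and 535). With an FPKM of at least 5, differences numbered 71, 262 and 332 over these 3 steps, and chicken genes 801 from E5 to E8 and 1077 from E3 to E8. Changes of at least 2 numbered 40, 27 and 16, then 220, 443 and 59, then 392, 584 and 100, in the same order, and 11 of the 27 were higher in pigeon at E5 and 79 of the 220 in chicken at E8. A mean FPKM of at least 20 without a pseudocount gave 83, 90 and 12, then 207, 739 and 66, then 299, 859 and 106, and from E3 to E5 66 of the 83, 61 of the 90 and 6 of the 12 were higher, against 286 of 431, 181 of 344 and 39 of 137 in the main counts. Inclusion of values of 0 gave 558 in pigeon from E3 to E5. Stricter filters and larger changes pass fewer genes by construction, and a smaller pseudocount enlarges the change of low genes.

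The correlation of E3 to E5 changes was 0.375 with an FPKM of at least 5 and 0.368 with a mean of 20, and that of pigeon E5 to E8 with chicken E3 to E5 was 0.199 with a mean of 20, and the cause was not tested. Shares reached at E5 also moved. With a pseudocount of 0.1, ganglion cell genes gave 46.2% in chicken and 35.8% in pigeon, synapse genes 29.7% in chicken and −0.598% in pigeon, a change of sign, pigment epithelium genes −111.1% in chicken and mesenchyme genes 8.85% in pigeon. With an FPKM of at least 5, synapse genes gave 21.6% in pigeon, pigment epithelium genes −216% in chicken and −25.5% in pigeon, mesenchyme genes −5.37% in chicken and heat shock genes 22.9% in pigeon. Median-ratio scaling gave −14.5% for chicken G2 and mitosis genes, and division of pigeon values 19.8% for pigeon mesenchyme genes. The cause was not tested.

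The number of lists outside the random range for the E3 to E8 difference was 2 with a pseudocount of 0.1 (main 5), and with the highest row of each symbol 8 for the E3 to E5 difference (main 5) and 5 for the E5 to E8 difference (main 3), and the cause was not tested. Of 162 list results, 155 kept their side of the range with a pseudocount of 0.1, 145 with the highest row and 162 with median-ratio scaling. The median-ratio factors lay between 0.990 and 1.01, so that scaling changed the values little. Of 513 named changes, 505 stayed on their side of 1 with a pseudocount of 0.1, 453 with 5, 511 with median-ratio scaling and 507 with quantile normalisation, and of 154 differences 149 with division of the pigeon values.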

Other observations

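Of the tests in this part, the one on short pigeon gene models was set before its result was seen, and those on sequences without a place, retinal expression, other tissues, scaling, level, loss of tissues and timing, with the spread of the timing values, were chosen after.

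Genes outside the main account also differed between the stages. CRYM, a thyroid hormone binding protein, was at 25.5 and 45.6 FPKM in chicken at E5 and E8 and at 107 and 474 in pigeon. MBP, a myelin protein, was at 0.413 in chicken at E8 and went from 6.87 to 44.2 in pigeon. In the Notch list, JAG1 was lower at E8 in both (−1.96 and −1.24), while HEY1 had changes of 0.64 and 1.49. The species differences of these genes were not tested, and their levels come from separately normalised tables.

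In chicken, 3418 rows were listed at 0 at all 3 stages, NEUROD4 among them. All 1470 rows on 21 unplaced or unlocalised sequences were at 0 (100%), against 1948 of 23238 other rows (8.38%). Of 387 symbols found only on those sequences, 154 were listed once in the pigeon table. For these 154, lack of expression in the retina is argued against, since 127 pigeon counterparts (82.5%) reached an FPKM of 5, against 77.3% of all pigeon symbols. The remaining symbols, and rows without a symbol, were not examined in this way. A candidate explanation is that reads were not assigned to those sequences, and 0 for NEUROD4 is then no sign of absence. For the other 1948 rows at 0, neither explanation was tested, nor was any other.

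Markers of pigment epithelium, blood, vessels and mesenchyme were lower at E8. Of members with an FPKM of at least 5 at E5, 32 of 40 in chicken (80%) and 17 of 21 in pigeon (81.0%) were lower by at least 1, against 3.87% and 6.19% of all genes. The median change of all genes farther from 0 was −0.00113. The deposited values were already centred, with median-ratio factors from 0.990 to 1.01 in chicken and 0.998 to 1.002 in pigeon. A median near 0 therefore cannot decide on scaling. A single factor at E8 would move all genes alike, and so cannot by itself set these markers apart from all genes. Other tissue in the E3 and E5 samples, scarcer at E8, may contribute, but its bound of over 80% was not passed in chicken. Lower expression in the retina itself would give the same shares, so at no value could this test tell it apart from other tissue. PDGFRA, COL5A1 and TGFBI were among the exceptions. Some of these genes also have retinal expression, and the labels describe whole retinas, so both stay open.

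Changes from E5 to E8 spread more widely across shared genes in pigeon (SD 0.79) than in chicken (SD 0.55), a ratio of 1.43, while from E3 to E5 the ratio was 0.954. The tables argue against the lower chicken level with a pseudocount, since the ratio was 1.49 at a mean FPKM of at least 20 without one. It was 1.64 in a first version that asked for 20 at every stage. Short pigeon models are argued against as well, with a ratio of 1.38 at 1500 bases or more. For loss of other tissues, 353 genes were higher in pigeon and 157 in chicken, a ratio of 2.25. Lower genes were also more frequent in pigeon, 302 against 194. A wider spread alone puts more genes past 1, so these counts cannot decide on loss of other tissues. A hypothesis is that the same changes come later in pigeon: among 154 genes higher at E8 than at E3 in both, the median part reached at E5 was 25.3% in chicken and 15.1% in pigeon, −10.2 points (−14.9 to −5.14 in the middle 95% of resampled gene sets, where genes are not independent replicates). A larger E8 change for any other reason could also lower this part, and 131 genes lower at E8 gave 16.2% and 16.4%, 0.208 points (−5.97 to 6.66), with 66 of them lower in pigeon, and 19.9% and 17.0% without other-tissue genes, so for them later and equal timing cannot be told apart. Stages were matched by day of incubation, and the timing values above do not settle whether the species differ in rate of maturation, which stays open.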
